A study of Mus musculus with 6 samples.

How the data were processed

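Gene expression was measured in 6 samples of cells sorted from the colon of mice that carry EGFP at the Mapt locus, 3 labelled EGFP-positive and 3 labelled EGFP-negative. The labels describe them as biological replicates, each made from cells of 2, 4 or 6 mice, without saying which replicate came from which number. Before the sort, the mice had received a fluorescent cholera toxin subunit in the celiac ganglion to trace neurons that project there, and were killed 3 to 4 days later. Per the labels' protocols, biotinylated cRNA was made from about 50 ng of total RNA and hybridised to 1-colour Affymetrix Mouse Genome 430 2.0 arrays.

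The deposited values are log2 expression values, 1 per probe set and array, which the authors made with RMA per the submitters' processing notes. The software version and the settings were not given in the sources used here. Column medians near 2, values down to 0.05 and unequal quartiles are unusual for RMA with quantile normalisation, so the method behind the values is uncertain and small differences between dim values carry little weight. The log2 scale was taken from the values, which ran from 0.05 to 15.2. Column medians were 1.98, 1.99 and 1.99 in the EGFP-positive replicates 1, 2 and 3 and 1.99, 1.91 and 1.96 in the EGFP-negative replicates. The upper quartiles ran from 4.08 to 4.86, so the columns did not share an identical distribution. Probe sets for a bacterial control transcript that was not added to the samples, TrpnX, read 1.00 to 1.48 and gave the background level. No normalisation was added to the deposited values for the comparison reported first. The number of arrays, and not a read depth, limits the precision.

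The table held 45101 probe sets, of which 64 were array controls. Gene symbols came from the platform annotation of the array, in which 34945 probe sets had 1 symbol, 932 had several and 9160 had none. A check against the RefSeq gene table led to 0 updated symbols. Probe sets with several symbols or none, and the controls, stayed out of the gene-level test. Each gene was represented by the probe set with the highest mean over the 6 arrays, which left 18193 genes. Of the 62 genes named by the rule below, 35 had several probe sets, and in 12 of these at least 1 probe set had a log2 difference of the opposite sign. These were Chrna4, Chrna7, Gabra3, Grik3, Kcna2, Kcnip4, Kitl, Klc1, Ncam1, Nos1, Rrm2 and Slc4a1. Other probe sets of Gfra1, Kcna1, Tbx3 and Cacna1d had the same sign but gave differences as small as 0.20, 0.03, 0.01 and -0.02. Of the genes in the fixed lists, some were not analysed here.

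The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) over all 18193 genes, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. A second count also asked for an absolute log2 difference of at least 1. All differences are EGFP-positive minus EGFP-negative. The p-values measure the spread among these 6 libraries, each of which pools several mice. Gene lists were tested with camera, which asks whether the genes of a list differ more than other genes, at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 30 lists. An estimated correlation and fry, which asks whether the list itself moves one way, were run beside it. Single measures per library, such as list means and control ratios, were compared with a two-sided exact permutation test, which with 3 against 3 cannot give a p under 0.1. It permutes the labels over all 6 libraries and so takes them as exchangeable, which libraries paired by number would not be. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

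The 30 lists, 13 of cell type markers and 17 of functions, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The cell type lists covered pan-neuronal genes, enteric neuron development, enteric glia, interstitial cells of Cajal, fibroblast-like and PDGFRA-positive cells, smooth muscle, macrophages, antigen presentation by MHC class II, lymphocytes and mast cells, endothelium, mesothelium, intestinal epithelium and red blood cells. Lists overlapped in part, so that 11 of 20 pan-neuronal genes, 10 of 30 axonal genes and 4 of 15 glial genes also stood in another list, and 0 of the macrophage, MHC class II and lymphocyte genes did. The rule named Mapt, Chat, Nos1, Vip, Tac1, Piezo1 and Piezo2, then the 6 largest and 6 lowest differences among genes past the threshold with groups that did not overlap, then of each cell type list the 2 members with the largest absolute difference, and of each functional list the highest and the lowest member. It gave 62 genes. Since 0 genes passed the threshold, the second part was empty. Genes named outside the rule are said to have been chosen after their values were seen.

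The labels number the replicates 1 to 3 in both groups without stating that a number marks shared mice or a shared day. The deviations from the group means of same-numbered libraries correlated across genes with r = 0.36, 0.32 and 0.42 for numbers 1, 2 and 3. All other pairs across the groups lay between -0.41 and -0.01, and 6 of 6 libraries correlated best with their own number. Deviations cancel within each group, so positive values for own numbers force negative ones elsewhere. The 6 matches are therefore not independent evidence of a pairing. Every pair exceeded the limit of 0.1 set beforehand, so the numbers were taken to pair the libraries, from the data and not from the design. The fit with the replicate number as a block is given wherever it changed a call.

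Alternatives covered the scaling of the arrays (centring on the median, a second quantile normalisation, centring on the mean of the cytosolic ribosome list), filters on dim genes, the treatment of several probe sets per gene, trend and robust variance estimates, array weights, the replicate block, a minimum fold of 1.5, other list tests and the removal of each library in turn. An alternative with the level of the hybridisation controls as a covariate was added after the data were seen. The test was run on simulated data for EGFP-positive against EGFP-negative, with the measured means and spreads of 18193 genes and 200 genes changed. It recovered 30.8% of genes changed by 1 on the log2 scale, 57.2% of those changed by 2, 86.6% of those changed by 4 and 94.2% of those changed by 6. The changed genes were drawn at random, with independent noise and no pairing, so these shares do not carry over to genes with a wide spread. In the measured data C1qc (-4.80) and Tyrobp (-4.71), with SDs of 3.30 and 2.72 in the EGFP-positive group, did not pass over all genes. For lists of 20 genes with no difference that shared a library-to-library spread of SD 1, the preset camera test made a call in 76% of 50 runs, and the estimated correlation did so in 4%. With a true shift of 1 added to such lists, the shares were 80% and 6%. Neither test told shifted from unshifted lists there, so a missing call with an estimated correlation does not argue that a list is unchanged.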

Results

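Cells of the mouse colonic myenteric plexus, the nerve network between the muscle layers of the gut wall, were sorted by EGFP fluorescence and profiled on arrays. EGFP was expressed from the Mapt locus, which encodes the microtubule protein tau and is active in neurons. The data hold 3 libraries labelled EGFP-positive, described in the labels as colonic neurons, and 3 labelled EGFP-negative, described as myenteric cells. Between 6182 and 7621 of 45101 probe sets exceeded a log2 value of 6 in a library, with the lowest number in EGFP-negative replicate 1. Values below are deposited log2 values, given for replicates 1, 2 and 3 in that order, and means are given with the SD of 3 libraries. The comparison asks which transcripts differ between the libraries of the 2 labels.

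Pan-neuronal transcripts were on average higher in 1 of the 3 libraries labelled EGFP-positive than in the other 5 libraries, and Mapt was near background in those 5. Mapt itself, which checks the labels, read 1.43, 1.32 and 5.55 in the libraries labelled EGFP-positive and 1.44, 1.64 and 1.38 in those labelled EGFP-negative. The background measured with TrpnX probe sets was 1.00 to 1.48. The log2 difference was 1.28 (SE 1.18), which did not pass (limma, Benjamini-Hochberg adjusted p = 1.00), and without EGFP-positive replicate 3 it was -0.11. The 4 Mapt probe sets gave differences of 0.06 to 1.28. They check the Mapt locus, which allele they detect was not tested, and EGFP itself was not analysed here. Mapt therefore went against the label in EGFP-positive replicates 1 and 2, and every direction below refers to the labels.

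The 20 pan-neuronal genes averaged 3.50, 3.48 and 6.41 in the libraries labelled EGFP-positive and 3.57, 3.68 and 3.97 in those labelled EGFP-negative. Map2, a dendritic microtubule protein, read 3.00, 3.63 and 7.13 against 2.37, 3.54 and 3.37. Ncam1, a neural adhesion molecule also made by glia, was higher in all 3 libraries labelled EGFP-positive, at 8.75 ± 1.14 (SD, n = 3) against 7.02 ± 0.47 (SD, n = 3). None of the 20 members passed over all genes, and 0 did so adjusted over the list alone. As a list they stood above other genes (mean log2 difference 0.72, limma camera adjusted p = 0.000293), but with adjusted p = 0.692 with an estimated correlation. Without EGFP-positive replicate 3 the direction turned, with adjusted p = 0.154, and the call was lost with arrays centred on the ribosome list (0.718) and with array weights (0.0703). The 14 genes of enteric neuron development averaged 5.63 ± 0.70 against 5.07 ± 0.39 (limma camera adjusted p = 0.0893). With the replicate number as a block the list passed, with adjusted p = 0.0216, and with adjusted p = 0.628 with an estimated correlation. Gfra1, a co-receptor for the growth factor GDNF, read 7.07, 7.25 and 9.06 against 3.71, 6.92 and 6.18, and Tbx3, a transcription factor, read 4.30, 4.88 and 7.93 against 3.03, 3.22 and 5.23. The development list also passed with median centring (0.0344), with trend and robust variances (0.048) and without EGFP-positive replicate 1 (0.0426) or 2 (0.0267), where the smallest value over all alternatives was adjusted p = 0.446 with an estimated correlation.

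Several transmitter genes had their highest value in the same library, and others did not. Nos1, the neuronal nitric oxide synthase, read 2.59, 2.80 and 7.74 in the libraries labelled EGFP-positive and 2.69, 3.44 and 4.26 in those labelled EGFP-negative. Vip, an inhibitory neuropeptide gene, read 6.12, 6.96 and 9.18 against 3.14, 7.36 and 6.77. Tac1, the gene of substance P, read 4.85, 4.52 and 6.52 against 4.14, 4.60 and 5.13. Sst, the somatostatin gene, read 2.06, 1.82 and 8.52 against 3.40, 5.03 and 5.63, so that its mean was lower in the group labelled EGFP-positive although its highest value lay there. Chat, the acetylcholine-synthesising enzyme, had 1 probe set that stayed between 1.13 and 1.54 in the 6 libraries, a level at which no difference can be read. Among receptors, Chrna7 read 1.12, 1.30 and 5.94 against 1.21, 1.53 and 1.56, while Chrna4 stayed between 1.39 and 1.74. Slc18a2, the vesicular monoamine transporter, read 3.86, 5.86 and 8.08 against 2.72, 5.83 and 5.61, and Slc6a2, the noradrenaline transporter, read 1.92, 2.30 and 1.70 against 2.18, 2.70 and 4.27. None of the lists for cholinergic transmission, other small transmitters and neuropeptides passed (limma camera adjusted p = 0.121, 0.198 and 0.459), and none of their members did over all genes. Other small transmitters were called higher among genes above the median level (0.0213), cholinergic genes without EGFP-positive replicate 1 (0.0476) or 2 (0.0309), and neuropeptides higher without EGFP-positive replicate 2 (0.0397) and lower without EGFP-positive replicate 3 (0.0176). Over all alternatives the smallest value of these 3 lists was adjusted p = 0.446 with an estimated correlation.

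Synaptic and axonal genes showed the pattern of the pan-neuronal list. The 25 genes of synaptic vesicles and release averaged 2.70, 2.67 and 5.05 in the libraries labelled EGFP-positive and 2.86, 2.95 and 3.10 in those labelled EGFP-negative. The 30 genes of the axonal cytoskeleton and transport averaged 4.74, 4.65 and 6.35 against 4.68, 4.65 and 4.92. Both lists passed as higher (limma camera adjusted p = 0.00891 and 0.000104), and with adjusted p = 0.692 for each with an estimated correlation. Without EGFP-positive replicate 3 both turned to lower, with adjusted p = 0.00114 and 0.708, and without EGFP-negative replicate 2 the synaptic list gave 0.102. Centring on the ribosome list ended both calls (0.825 and 0.25), and the synaptic call was also lost among genes above the median level (0.204) and with array weights (0.269). Syt11, a synaptotagmin, read 6.34, 6.19 and 8.24 against 3.70, 5.33 and 6.24, and Rims1, an active zone protein, read 4.18, 3.84 and 6.94 against 5.47, 4.57 and 7.82. Klc1, a kinesin light chain, was 6.96 ± 0.23 (SD, n = 3) against 7.17 ± 0.12 (SD, n = 3), a direction that turned when arrays were centred on the ribosome list. In the replicate block 1 axonal member passed adjusted over the list alone, Map1b, a microtubule protein chosen for naming after its value was seen.

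The mean of the enteric glia list, markers of the supporting cells of the plexus, was higher in all 3 libraries labelled EGFP-positive, and 6 of its 15 members had groups that did not overlap. The list averaged 6.23, 5.88 and 8.01, against 4.19, 5.69 and 5.34, and the list mean gave an exact permutation p = 0.1, the smallest possible. As a list they rose (mean log2 difference 1.64, limma camera adjusted p = 1.52e-10), with adjusted p = 0.542 with an estimated correlation. In all 3 same-numbered pairs the library labelled EGFP-positive was higher, although in pair 2 by only 0.20. Libraries paired in this way would not be exchangeable, as the permutation test takes them to be. EGFP-negative replicate 1 had the lowest list mean and also the fewest probe sets above a log2 value of 6 (6182). The potassium channel gene Kcna1 had a log2 difference of 3.05 (SE 1.02), and Sostdc1, a secreted BMP and Wnt antagonist, one of 2.52 (SE 0.92). Neither passed over all genes or adjusted over the list alone, and 0 of the 15 members did. Without EGFP-negative replicate 1 the log2 differences of Kcna1 and Sostdc1 were 2.02 and 1.69. Scn7a, a sodium channel gene that glia express, read 9.48, 9.97 and 11.65 against 6.31, 9.09 and 8.63. Kcna2, a partner subunit of Kcna1, read 8.32, 8.17 and 10.27 against 3.76, 6.92 and 6.28.

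Immune cell transcripts were lower in the libraries labelled EGFP-positive. The 15 macrophage genes averaged 6.04, 3.45 and 2.38 there and 7.26, 7.73 and 6.11 in the libraries labelled EGFP-negative. Tyrobp, a signalling adaptor of myeloid cells, was 4.23 ± 2.72 (SD, n = 3) against 8.94 ± 0.67 (SD, n = 3), and C1qc, a complement component made by macrophages, was 2.77 ± 3.30 against 7.57 ± 1.28. The 8 genes of antigen presentation by MHC class II averaged 4.87, 3.88 and 3.26 against 5.69, 6.53 and 6.50, and all 8 had groups that did not overlap. H2-Eb1, an MHC class II chain, had a log2 difference of -3.05 (SE 0.72), and H2-DMa, which helps load peptides, read 3.27, 1.70 and 1.37 against 3.78, 7.07 and 5.70. The second H2-DMa probe set gave a difference of only -0.52. The 14 lymphocyte and mast cell genes averaged 1.79, 1.34 and 1.19 against 2.28, 3.34 and 3.93. Jchain, the joining chain of antibodies made by plasma cells, read 2.86, 0.16 and 0.13 against 5.25, 10.33 and 8.71. Its values in EGFP-positive replicates 2 and 3 lay below the TrpnX background, so the size of the difference cannot be read exactly. Cd79b, a B cell receptor component, read 2.27, 1.06 and 1.55 against 3.25, 5.97 and 7.59.

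All 3 immune lists fell as lists (limma camera adjusted p = 1.72e-11, 1.72e-11 and 6.41e-09 for macrophage, MHC class II and lymphocyte genes), each with adjusted p = 0.542 with an estimated correlation. Each list mean was lower in all 3 same-numbered pairs and gave an exact permutation p = 0.1, the smallest possible. The permutation takes the libraries as exchangeable, which paired libraries would not be. Over all genes 0 members passed. Adjusted over the list alone, 5 of 15 macrophage genes, 7 of 8 MHC class II genes and 0 of 14 lymphocyte and mast cell genes fell. With the replicate number as a block, 13 macrophage genes did so and 7 MHC class II genes.

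**Figure D1:**
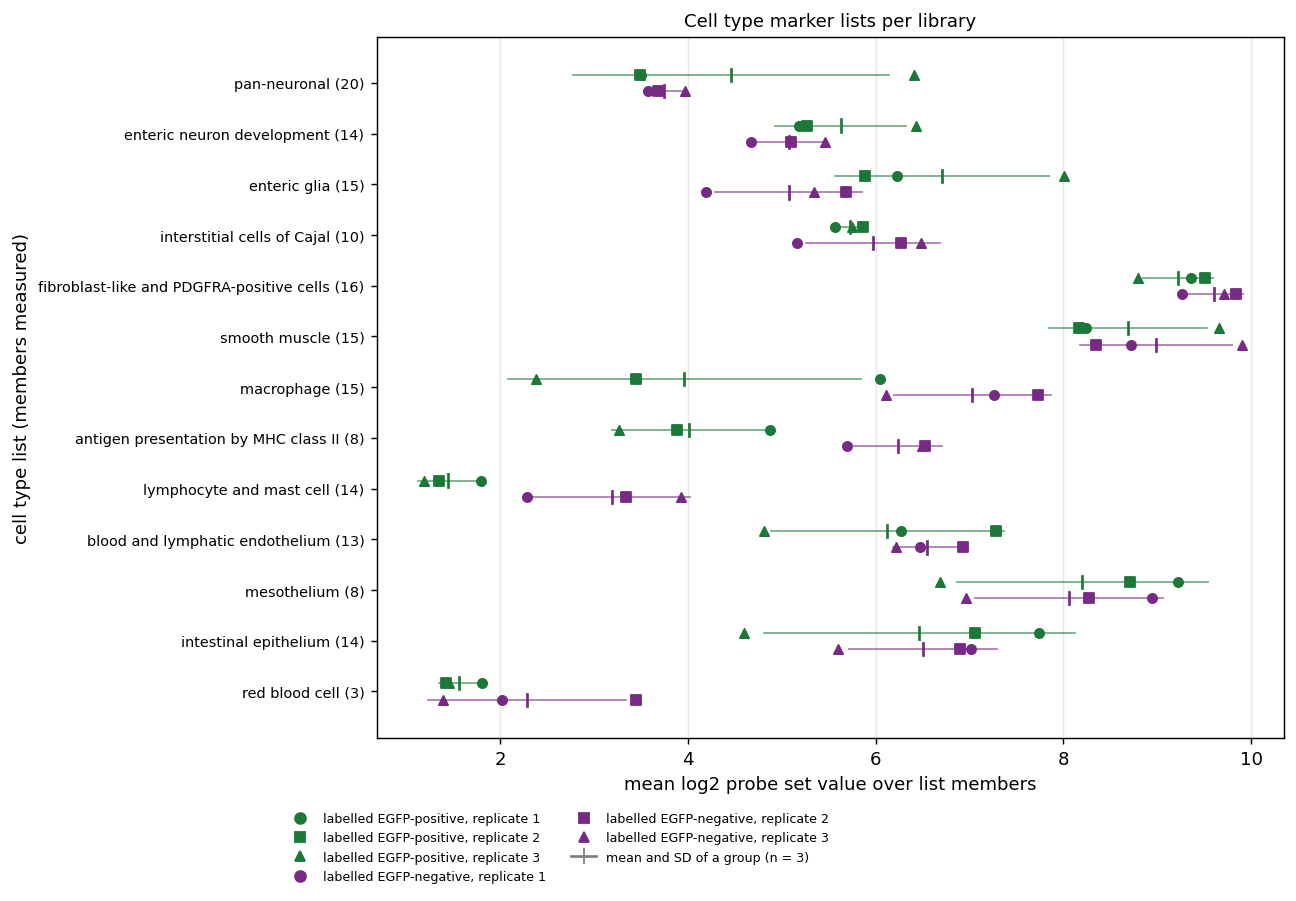
Mean log2 probe set value over the measured members of each of 13 cell type lists, 1 point per library, with the mean and SD of each group of 3. The pan-neuronal mean reached 6.41 in EGFP-positive replicate 3 and lay between 3.48 and 3.97 in the other libraries, and the lymphocyte and mast cell means of the EGFP-positive libraries, 1.19 to 1.79, all lay below the EGFP-negative ones, 2.28 to 3.93.

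Transcripts of muscle, connective tissue and mesothelium were abundant in both groups. Smooth muscle genes averaged 8.69 ± 0.84 (SD, n = 3) in the libraries labelled EGFP-positive and 8.99 ± 0.81 (SD, n = 3) in those labelled EGFP-negative. Genes of fibroblast-like and PDGFRA-positive cells averaged 9.22 ± 0.37 against 9.61 ± 0.30, those of mesothelium 8.20 ± 1.34 against 8.06 ± 1.01, and those of endothelium 6.12 ± 1.24 against 6.54 ± 0.36. Intestinal epithelium averaged 6.47 ± 1.65 against 6.50 ± 0.79, with a median difference of opposite sign (0.01) to the mean difference (-0.04). Interstitial cells of Cajal, the pacemaker cells of the gut, averaged 5.73 ± 0.15 against 5.97 ± 0.71, and the 3 red blood cell genes averaged 1.56 ± 0.21 against 2.29 ± 1.05. None of these 7 lists passed (limma camera adjusted p = 0.121 to 0.782). With the replicate block, smooth muscle (adjusted p = 0.00394, lower in 3 of 3 pairs) and endothelium (adjusted p = 0.0435, lower in 2 of 3 pairs) did, with adjusted p = 0.628 and 0.649 with an estimated correlation. When arrays were centred on the ribosome list, which shifts all differences alike, the signs of the smooth muscle, Cajal and epithelium means turned. Relative to other genes, smooth muscle (0.000364), Cajal (0.0148), fibroblast (0.0148) and endothelium (3.74e-05) genes were then called lower. Median centring also called fibroblast (0.0084) and endothelium (0.0129) genes lower. Without EGFP-positive replicate 3, mesothelium (0.000433) and epithelium (2.96e-05) were called higher and smooth muscle lower (0.000309). Fibroblast genes were called lower without EGFP-positive replicate 1 (0.0369) or 2 (0.0209), endothelium without EGFP-positive replicate 2 (3.29e-06) and among genes above the median level (0.0245), and smooth muscle without EGFP-negative replicate 2 (0.0141). Over all alternatives the smallest values were adjusted p = 0.446 with an estimated correlation for endothelium, 0.454 for fibroblast, 0.526 for Cajal and 0.604 for smooth muscle, mesothelium and epithelium genes.

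Individual markers of these cells varied widely within the groups. Cnn1, a smooth muscle calponin, read 8.44, 7.41 and 10.15 against 9.46, 7.91 and 10.54, and Pcp4, a calmodulin-binding protein, read 6.94, 7.10 and 8.90 against 9.22, 8.15 and 9.40. Muc2, the goblet cell mucin, read 10.60, 8.80 and 5.91 against 5.30, 9.20 and 6.93, and Car4, a carbonic anhydrase, read 5.87, 3.72 and 2.33 against 7.43, 4.84 and 4.27. In the replicate block Car4 passed adjusted over the list alone. Kit, the receptor that marks Cajal cells, read 5.46, 5.10 and 3.40 against 3.16, 7.42 and 7.11, and Prkcq read 2.35, 3.46 and 1.90 against 2.71, 4.69 and 4.52. Dpt, a matrix protein of fibroblasts, was 10.33 ± 0.62 (SD, n = 3) against 11.38 ± 0.54 (SD, n = 3), and P2ry1, a purine receptor, was 1.65 ± 0.39 against 3.60 ± 1.60. Emcn and Pecam1, both of endothelium, had log2 differences of -1.29 (SE 0.80) and -0.92 (SE 0.56). Those of Krt19 and Upk1b, both of mesothelium, were 0.24 (SE 0.68) for each, and that of Slc4a1, of red cells, was -0.68 (SE 0.34). Alas2, also of red cells, stood out in 1 library, at 1.75, 1.25 and 1.31 against 2.20, 5.87 and 0.97.

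Piezo2, a mechanically gated ion channel, separated the groups in every library. It read 5.15, 5.24 and 4.64 in the libraries labelled EGFP-positive and 3.56, 3.64 and 3.46 in those labelled EGFP-negative, a log2 difference of 1.46 (SE 0.19). It did not pass over all genes (limma, Benjamini-Hochberg adjusted p = 0.951) and was the 1 of 26 genes of mechanically gated and related channels that passed adjusted over the list alone (adjusted p = 0.00934). Its levels did not follow the neuronal lists, since EGFP-positive replicate 3 held the lowest of the 3 values. The second Piezo2 probe set gave a difference of 0.50. Piezo1, the related channel, was 7.58 ± 0.67 (SD, n = 3) against 7.74 ± 0.51 (SD, n = 3), a difference within the spread whose sign turned when arrays were centred on the ribosome list. Kcnk2, a stretch-sensitive potassium channel, read 2.28, 2.78 and 2.22 against 2.95, 5.35 and 4.45. The list did not pass (limma camera adjusted p = 0.121), but was called higher without EGFP-positive replicate 2 (0.0358), with adjusted p = 0.446 with an estimated correlation.

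**Figure D2:**
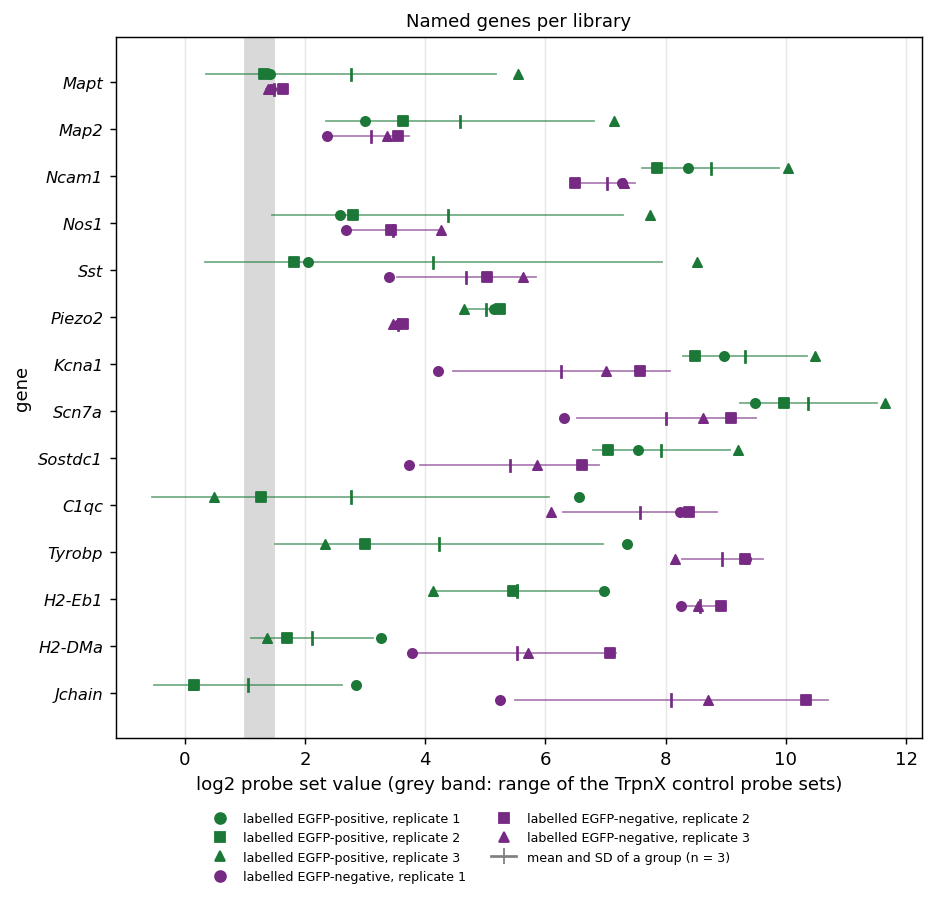
Log2 values of 14 named genes in each library, with the mean and SD of each group of 3 and, in grey, the range of the TrpnX control probe sets (1.00 to 1.48). Mapt, Map2, Nos1 and Sst reach their highest value in EGFP-positive replicate 3, Piezo2 lies between 4.64 and 5.24 in EGFP-positive and between 3.46 and 3.64 in EGFP-negative libraries, and Jchain ranges from 0.13 to 10.33.

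Of the other excitability genes, the lists of voltage-gated sodium and calcium channels, potassium and pacemaker channels, and ligand-gated receptors had mean log2 differences of 0.30, 0.35 and 0.29 and did not pass (limma camera adjusted p = 0.0939, 0.0746 and 0.0570). Neurotrophic and endothelin signalling had one of 0.41 (adjusted p = 0.0669). With the replicate block the sodium and calcium channels (adjusted p = 0.0456) and the neurotrophic list (adjusted p = 0.0484) passed as higher, with adjusted p = 0.649 and 0.628 with an estimated correlation. Ligand-gated receptors also passed with median centring (0.0344), a second quantile normalisation (0.0306), trend and robust variances (0.0273), camera on ranks (0.0409), without _x_at and _s_at probe sets (0.0491) and without EGFP-positive replicate 1 (0.0178) or 2 (0.00635) or EGFP-negative replicate 1 (0.0387). Potassium channels passed with median centring (0.0354) and without EGFP-positive replicate 1 (0.00975) or 2 (0.00569) or EGFP-negative replicate 3 (0.0303). Sodium and calcium channels passed with camera on ranks (0.0441), without _x_at and _s_at probe sets (0.0384) and without EGFP-positive replicate 1 (0.00975) or 2 (0.0151). The neurotrophic list passed with a second quantile normalisation (0.0306), trend and robust variances (0.0381), without _x_at and _s_at probe sets (0.0491) and without EGFP-positive replicate 1 (0.0415) or 2 (0.0209) or EGFP-negative replicate 3 (0.0429). Over all alternatives the smallest values were adjusted p = 0.446 with an estimated correlation for the ligand-gated, potassium and neurotrophic lists and 0.512 for sodium and calcium channels. Without EGFP-positive replicate 3 none of these 3 channel and receptor lists passed. Cacna1d, an L-type calcium channel gene, read 2.40, 2.01 and 2.40 against 2.59, 4.74 and 4.37. Grik3, a kainate receptor gene, read 4.77, 5.27 and 7.61 against 3.70, 4.64 and 4.93, and Gabra3, of a GABA receptor, read 3.91, 5.67 and 3.19 against 3.66, 6.32 and 5.38. Kcnip4, a potassium channel partner, read 1.80, 2.17 and 5.29 against 3.03, 3.21 and 5.06, and Kitl, the ligand of Kit, had a log2 difference of -0.59 (SE 0.42).

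Housekeeping lists moved by small amounts. The 23 cytosolic ribosome genes averaged 9.49, 9.50 and 9.12 in the libraries labelled EGFP-positive and 9.82, 9.77 and 9.65 in those labelled EGFP-negative. They fell as a list (mean log2 difference -0.37, limma camera adjusted p = 1.52e-10), with adjusted p = 0.542 with an estimated correlation, and were lower in 3 of 3 pairs. The 27 genes of mitochondrial respiration averaged 9.13 ± 0.05 (SD, n = 3) against 9.26 ± 0.09 (SD, n = 3) and also fell (limma camera adjusted p = 0.00866), with adjusted p = 0.663 with an estimated correlation. The sign of the mitochondrial mean turned when arrays were centred on the ribosome list (0.24). Its call was lost without EGFP-positive replicate 3 (adjusted p = 0.0931) and without EGFP-negative replicate 3 (adjusted p = 0.116). It was also lost with arrays centred on the median (0.0851) or on the ribosome list (0.55), with a second quantile normalisation (0.754) and among genes with 3 arrays above 6 (0.0669). Ndufv2, of respiratory complex I, read 9.13, 9.07 and 9.10 against 9.57, 9.56 and 9.59, and Uqcrc1, of complex III, had a log2 difference of 0.22 (SE 0.26). Rps27 was the 1 ribosomal gene that passed adjusted over the list alone (adjusted p = 0.0422), and it lost this call with the replicate block (adjusted p = 0.0771). Its values of 1.68 to 2.62 lay just above background, and Rps16 stayed at background, between 0.89 and 1.17.

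Stress, injury and growth lists did not pass in the comparison as fixed. Immediate early and heat shock genes averaged 8.46 ± 0.03 (SD, n = 3) against 8.50 ± 0.12 (SD, n = 3) (limma camera adjusted p = 0.928). Jun, an immediate early transcription factor, had a log2 difference of 0.52 (SE 0.40), and Zfp36, an mRNA decay factor, one of -0.50 (SE 0.21). The axon injury response (mean log2 difference 0.26, adjusted p = 0.198) included Atf3, at 7.61, 7.13 and 6.67 against 8.02, 7.55 and 6.43. The cell cycle list had adjusted p = 0.462, with Bub1 at -0.52 (SE 0.94) and Rrm2 at 0.28 (SE 0.24). The cell cycle list was called lower (1.98e-05) and the injury list higher (0.0225) without EGFP-positive replicate 2, each with adjusted p = 0.446 with an estimated correlation. Extracellular matrix genes had adjusted p = 0.216, 0.0135 with a second quantile normalisation and 0.0163 without EGFP-negative replicate 3 (smallest over all alternatives adjusted p = 0.671 with an estimated correlation), with Timp3, an inhibitor of matrix proteases, at 0.73 (SE 0.23) and Lum at -0.53 (SE 0.43). The interferon response had adjusted p = 0.304, and with the replicate block it passed as lower (adjusted p = 0.0247, lower in 3 of 3 pairs, adjusted p = 0.628 with an estimated correlation). The interferon list was also called lower with ribosome centring (0.0472), where its mean turned, and without EGFP-positive replicate 2 (0.0409) or EGFP-negative replicate 3 (0.0303), with adjusted p = 0.512 or more with an estimated correlation in all alternatives. In the replicate block Rsad2, an antiviral gene at 6.80, 6.20 and 5.26 against 7.49, 7.08 and 6.32, passed adjusted over the list alone, while Stat2 had a difference of 0.49 (SE 0.32). The signs of the immediate early, cell cycle and interferon means turned when arrays were centred on the ribosome list.

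Over the whole transcriptome, 0 of 18193 genes passed (limma, Benjamini-Hochberg adjusted p of the first gene 0.340), and 0 passed with an absolute log2 difference of at least 1. At an unadjusted p under 0.05 there were 893 genes, 269 higher and 624 lower in the libraries labelled EGFP-positive, where chance gives about 910. Centring on the ribosome list moved the median difference of all genes from -0.02 to 0.36, so that 1763 of 1974 genes at an unadjusted p under 0.05 were then higher. The replicate block also gave 0 genes, with 1345 at an unadjusted p under 0.05, and a test against a minimum fold of 1.5 gave 0. The groups did not overlap in 1658 genes, or 9.11%, where chance gives 10%. Both chance figures assume exchangeable libraries, which libraries paired by number would not be. The other splits that part all 3 pairs gave 319, 218 and 520 genes at an unadjusted p under 0.05. Splits that part only 1 pair gave 477 to 1525, in part above the 893 of the real split, so these counts do not show that the real grouping exceeds chance. Without EGFP-positive replicate 1, 2 genes passed, both chosen for naming because they are all that did: Ccr2, a chemokine receptor of monocytes, and Fermt3, an integrin activator of blood cells, with limma adjusted p = 0.0251 and 0.0108. Fermt3 then had a log2 difference of -5.72, and Ccr2 read 0.84 and 1.21, at background, in the remaining libraries labelled EGFP-positive. The preset camera test called 9 of 30 lists, 4 higher and 5 lower, and 15 with the replicate block, whereas an estimated correlation and fry called 0. In the simulation the estimated correlation rarely called lists that were truly shifted and shared a spread, so its 0 calls do not argue that the lists are unchanged. The preset test called 76% of such lists without a shift and 80% with one, so its calls alone do not show that lists changed. Of the 10 splits into 3 and 3, 9 called at least as many lists as the real one, with 17 as the highest of the others.

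Correlations within the groups overlapped with those between the groups. Pearson's r over genes, which are not independent replicates, was 0.939 to 0.975 among the libraries labelled EGFP-positive, 0.953 to 0.974 among those labelled EGFP-negative and 0.924 to 0.974 between the groups. The principal component with the largest share, 39.2% of the variance, placed EGFP-positive replicate 3 at 86.2 and the other libraries between -44.7 and 8.63.

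Signs of RNA quality and array signal did not separate the groups. The log2 difference between 3' and 5' probe sets of Gapdh was 1.29, 1.06 and 0.97 in the libraries labelled EGFP-positive and 1.00, 2.47 and 0.77 in those labelled EGFP-negative (exact permutation p = 0.9). That of Actb was 2.39 ± 0.23 (SD, n = 3) against 2.28 ± 0.66 (SD, n = 3), also with an exact permutation p = 0.9. Hybridisation controls, added in equal amounts to each array, averaged 10.82, 9.71 and 10.18 against 12.54, 10.03 and 9.23. An 18S ribosomal RNA probe set read 9.74, 9.51 and 9.61 against 12.85, 7.65 and 9.40. None of 7 such measures gave an exact p under 0.5, and each had a Benjamini-Hochberg adjusted p of 1.

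**Figure D3:**
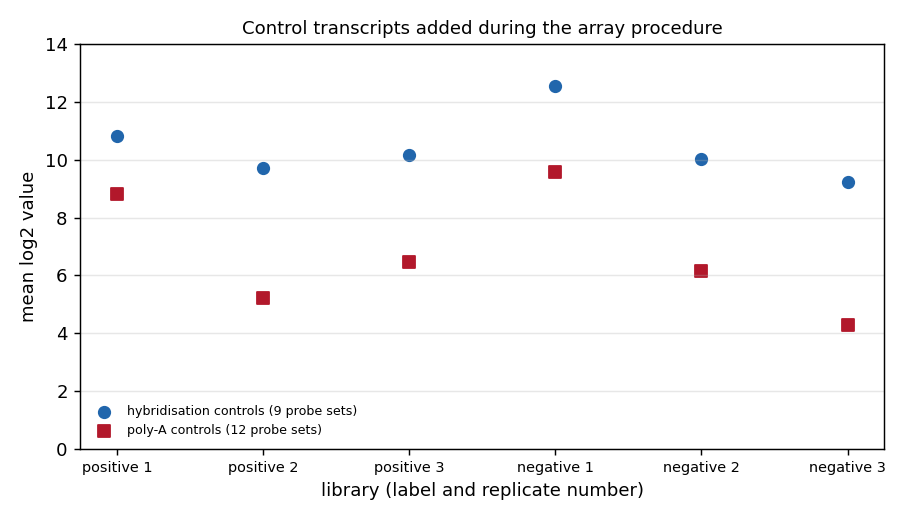
Mean log2 value of the 9 hybridisation control and 12 poly-A control probe sets in each library. Replicate 1 has the highest level in both groups, 10.82 and 12.54 for the hybridisation controls and 8.83 and 9.60 for the poly-A controls.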

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

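The covariate for the level of the hybridisation controls and the estimated correlation combined with each alternative were chosen after seeing the data, and the other alternatives were fixed earlier. Of the 1009 values of the 62 named genes under alternatives, 986 kept their direction and 23 reversed, and 0 reached adjusted p 0.05 (limma, Benjamini-Hochberg). When 1 library was left out, 45 of the 62 genes moved by over 1.5 times, 10 of them changing sign. The 9 called lists kept their call in 144 of 178 alternatives, lost it in 31 and reversed in 3. All alternatives except the estimated correlation and fry kept camera at its preset correlation of 0.01, so the 144 do not test that setting. With an estimated correlation or fry, 0 of the 9 lists kept their call. The lists that were not called stayed so with the same direction in 314, became called in that direction in 58 and reversed in 42, of which 1 was a call (neuropeptides lower without EGFP-positive replicate 3, 0.0176). The lymphocyte and mast cell and the synaptic list had too few members for a value among genes with 3 arrays above a log2 value of 6. For the changes below the cause was not tested, except that a removed library leaves fewer samples. Signal over background limits the dim lists, since TrpnX probe sets read up to 1.48.

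The adjusted p of the glia list (limma camera and fry) ran from 7.54e-16 to 0.542, that of the macrophage list from 5.83e-35 to 0.542, MHC class II from 4.09e-26 to 0.542, lymphocyte and mast cell from 1.22e-15 to 0.542 and cytosolic ribosome from 1.96e-10 to 0.542. These 5 lists lost their call with an estimated correlation and with fry and with no other alternative. For the ribosome list, centring on its own mean removes the list's own change, so that alternative is no test of it. The ranges of the other 4 were 1.11e-07 to 0.799 for the pan-neuronal and the axonal list, 9.83e-06 to 0.825 for the synaptic list and 0.00141 to 0.754 for mitochondrial respiration. With an estimated correlation 0 lists were called, and adjusted p was 0.692 for the pan-neuronal, synaptic and axonal lists, 0.542 for glia, macrophage, MHC class II, lymphocyte and mast cell and ribosome, and 0.663 for mitochondrial respiration. Combined with each other alternative, the estimated correlation also called 0 lists, with a smallest adjusted p of 0.0756 (MHC class II and ribosome, arrays centred on the ribosome list). The value of the ribosome list rests on the same centring on its own mean. With fry 0 lists were called, with 0.799 for the 3 neuronal lists, 0.463 for glia, 0.352 for macrophage, ribosome and mitochondrial respiration, 0.297 for MHC class II and 0.326 for lymphocyte and mast cell.

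Scaling changed the following adjusted p values (limma camera). Directions of lists in this and the following paragraphs are those of camera, relative to other genes, and can differ from the sign of the list mean. With arrays centred on the median, the epithelium list went from above to below other genes (0.832) while its mean difference went from -0.04 to 0.03, and mitochondrial respiration lost its call (0.0851). With a second quantile normalisation, the immediate early list turned to higher (0.323) and mitochondrial respiration gave 0.754. With arrays centred on the ribosome list, the log2 differences of Atf3, Chrna4, Klc1 and Piezo1 turned to 0.17, 0.20, 0.16 and 0.21. The pan-neuronal (0.718), synaptic (0.825), axonal (0.25) and mitochondrial (0.55) lists lost their call. The mesothelium and neuropeptide lists (0.455 each), epithelium (0.0747), sodium and calcium channels and extracellular matrix (0.919 each), potassium channels (0.976) and axon injury (0.762) then lay lower than other genes.

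Scaling also added calls. Median centring called enteric neuron development (0.0344), ligand-gated receptors (0.0344) and potassium channels (0.0354) higher and fibroblast (0.0084) and endothelium (0.0129) genes lower. A second quantile normalisation called ligand-gated receptors and neurotrophic signalling (0.0306 each) and extracellular matrix (0.0135) higher. Centring on the ribosome list called smooth muscle (0.000364), Cajal and fibroblast (0.0148 each), endothelium (3.74e-05) and interferon (0.0472) genes lower.

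Among genes above the median level the synaptic list gave 0.204 (limma camera adjusted p), and other small transmitters (0.0213, higher) and endothelium (0.0245, lower) were called. Trend and robust variances called enteric neuron development (0.048), ligand-gated receptors (0.0273) and neurotrophic signalling (0.0381) higher. Camera on ranks called ligand-gated receptors (0.0409) and sodium and calcium channels (0.0441), and leaving out _x_at and _s_at probe sets called both of these (0.0491 and 0.0384) and neurotrophic signalling (0.0491). Among genes with 3 arrays above 6, the Cajal and immediate early lists turned to higher (0.875 each) and mitochondrial respiration gave 0.0669. With the mean of a gene's probe sets Klc1 had a log2 difference of 0.12 and the immediate early list turned (0.638), as it did with trend and robust variances (0.957) and with the covariate (0.647). With array weights Nos1 had a log2 difference of -0.053 and Piezo1 of 0.080. The pan-neuronal (0.0703) and synaptic (0.269) lists then lost their call, and endothelium (0.699), neuropeptides (0.563), immediate early (0.743) and cell cycle (0.221) turned. The replicate block called 15 lists, among them the 9, turned the epithelium list (0.892) and changed no other call than those given in the report.

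Leaving out each library in turn gave ranges. Genes past adjusted p 0.05 numbered 0 to 2 (limma), with 2 without EGFP-positive replicate 1, also at an absolute log2 difference of at least 1. Called lists numbered 9 to 22, with 16 without EGFP-positive replicate 1 and 22 without EGFP-positive replicate 2. Log2 differences ran from -0.11 to 2.00 for Mapt, -0.65 to 0.14 for Atf3, -1.43 to 0.060 for Bub1, -0.035 to 0.16 for Chat, -0.22 to 2.19 for Chrna7 and -0.21 to 0.91 for Krt19. They ran from -0.77 to 1.81 for Nos1, -0.46 to 0.21 for Piezo1, -2.75 to 0.60 for Sst and -0.24 to 0.86 for Upk1b. The lowest values of Mapt, Chat, Chrna7, Nos1 and Sst came without EGFP-positive replicate 3. The group difference in the Gapdh 3' to 5' measure ran from -0.632 to 0.218, the latter without EGFP-negative replicate 2.

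Over the same removals the adjusted p (limma camera) ran from 1.11e-07 to 0.154 for the pan-neuronal list, 9.83e-06 to 0.102 for the synaptic, 1.11e-07 to 0.708 for the axonal and 0.00141 to 0.116 for the mitochondrial list. For cell types it ran from 0.141 to 0.916 for Cajal cells, 0.0209 to 0.874 for fibroblast-like cells, 0.000309 to 0.985 for smooth muscle, 3.29e-06 to 0.363 for endothelium, 0.000433 to 0.974 for mesothelium and 2.96e-05 to 0.759 for epithelium. It ran from 0.0267 to 0.804 for enteric neuron development. For transmitters and channels it ran from 0.0309 to 0.411 for cholinergic genes, 0.0176 to 0.756 for neuropeptides, 0.00975 to 0.507 for sodium and calcium channels, 0.00569 to 0.345 for potassium channels 0.0358 to 0.272 for mechanically gated channels and 0.00635 to 0.93 for ligand-gated receptors. For the others it ran from 0.0209 to 0.507 for neurotrophic signalling, 0.0163 to 0.567 for extracellular matrix, 0.0225 to 0.56 for axon injury, 0.283 to 0.957 for immediate early genes, 1.98e-05 to 0.96 for the cell cycle and 0.0303 to 0.917 for the interferon response. Without EGFP-positive replicate 3 the pan-neuronal, synaptic, axonal, fibroblast, endothelium, cholinergic, neuropeptide, sodium and calcium, potassium, ligand-gated, axon injury, cell cycle and interferon lists turned.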

Other observations

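The tests of the neuronal and immune patterns below and the count of gene splits were chosen only after the result was seen, as were the genes named in this paragraph and the next. Genes outside the lists with low unadjusted p values included some that were lower in every library labelled EGFP-positive. Il1b, an inflammatory cytokine, read 4.40, 2.01 and 4.11 against 8.27, 8.50 and 8.31 in the libraries labelled EGFP-negative. Srgn, a granule proteoglycan, had a log2 difference of -2.41 (SE 0.23), and Mefv, the pyrin gene of myeloid cells, read 1.26, 1.16 and 1.14 against 2.58, 2.61 and 2.52. Mefv had the smallest adjusted p of all genes (limma, Benjamini-Hochberg 0.340). Higher in every library labelled EGFP-positive were Mbp, a myelin protein, with a log2 difference of 2.13 (SE 0.45), Malat1, a nuclear RNA, with 1.57 (SE 0.31), and Map1b, with 1.41 (SE 0.41). The glial genes Erbb3 and Sox10 had differences of 2.02 (SE 0.58) and 1.82 (SE 0.59). None of these genes passed over all genes.

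Several neuropeptide and transmitter genes were far above background in EGFP-positive replicate 3 alone. Grp read 1.89, 0.80 and 7.50 in the libraries labelled EGFP-positive and 2.32, 3.11 and 3.21 in those labelled EGFP-negative, Nmu read 1.60, 0.86 and 5.18 against 1.97, 1.98 and 1.04, and Slc17a6, a vesicular glutamate transporter, read 1.56, 1.28 and 4.55 against 1.65, 1.68 and 1.47. Nts, the neurotensin gene, went with the replicate number instead, at 7.10, 6.42 and 1.34 against 7.42, 6.64 and 1.48.

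Pan-neuronal transcripts were high in EGFP-positive replicate 3 and not in the other libraries labelled EGFP-positive. A swap that left a library rich in neuronal transcripts under the EGFP-negative label needs such a library near EGFP-positive replicate 3. The nearest lay at 0.163 (bootstrap interval over list genes 0.0323 to 0.276) on a scale from 0, replicates 1 and 2, to 1, replicate 3. A swap between libraries equally low in these transcripts would leave this value much the same, so it stays open. The list's median lay -2.86 and -3.07 from replicate 3 in replicates 1 and 2, against -0.12 and -0.02 for level-matched random lists. Of 10000 such lists 0% lay as low in either library, so a loss shared by equally bright genes does not account for the drop. Column medians were already alike in the deposited values, so an overall loss of labelled RNA would not show here and was not tested. Few neurons among the cells of replicates 1 and 2 stay open, untested: their list mean differed by -0.249 (-0.526 to 0.029) from that of the libraries labelled EGFP-negative, which restates the pattern. Wrong labels on both libraries without a partner stay open too. Piezo2 (5.15 and 5.24 against 3.46 to 3.64), Il1b (4.40 and 2.01 against 8.27 to 8.50) and the MHC class II mean (4.87 and 3.88 against 5.69 to 6.53) separated both from the libraries labelled EGFP-negative. They were picked here because they separate the labels, so they cannot test the labels. In the MHC class II mean, replicate 1 (4.87) lay nearer to EGFP-negative replicate 1 (5.69) than to EGFP-positive replicate 3 (3.26). In the macrophage mean, replicate 1 (6.04) lay next to EGFP-negative replicate 3 (6.11) and far from EGFP-positive replicate 3 (2.38).

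The macrophage and MHC class II lists were lower in all 3 libraries labelled EGFP-positive. Bootstrap intervals in this section resample the genes of the lists and not the libraries, so they hold no spread between libraries. Dilution of all other cell types by neurons would lower fibroblast, smooth muscle, endothelium and mesothelium genes alike, but over all 6 libraries the immune lists lay a further -2.49 (bootstrap interval -3.05 to -1.94) below these. Between the libraries numbered 3, 1 against 1, they lay a further -2.80 (-3.53 to -2.07) below, with -0.75 for the other lists. Without EGFP-positive replicate 3, the library with high neuronal transcripts, the immune lists still lay a further -2.06 (-2.53 to -1.57) lower. With the hybridisation control level as a covariate the mean change of the 2 lists was -2.69 (-3.18 to -2.18), against -2.78 without it. The control level differed little between the groups, at 10.24 for EGFP-positive against 10.60 for EGFP-negative, so the covariate could hardly move this change. It therefore cannot decide on the amount of labelled RNA, which stays open. A removal of immune cells by the sort gate may remain as an explanation and was not tested.

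Libraries with the same replicate number resembled each other across the groups. After removal of the trend on the hybridisation controls within each group the pair correlations were -0.742, 0.277 and 0.264, but simulated pairs that do not depend on the controls gave a lowest value of -0.704, so the removal itself fixes the outcome. The simulated check was added after the result was seen. The amount of labelled RNA and shared mice or a shared day therefore cannot be told apart here, and no biological explanation was tested.

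The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past adjusted p 0.05 (limma, Benjamini-Hochberg) 10 of the 10 splits gave as many as the real one, which gave 0, with 0 as the highest of the others, an outcome that a count of 0 fixes. For gene lists 9 of the 10 splits gave as many as the real one, which called 9, with 17 as the highest of the others. Of the splits that part all 3 same-numbered pairs, the real one gave 893 genes at an unadjusted p under 0.05, and 1345 with the replicate block, where 15 lists were called. The other 3 gave 319, 218 and 520, and with the block 578, 490 and 839 with 14, 12 and 12 lists. Each of these puts libraries of both labels in each group. Splits that part only 1 pair gave 477 to 1525 genes at an unadjusted p under 0.05 without the block, so the real split was not the highest of the 10. The pairing was taken from these same data, and so few splits cannot show that the real one exceeds chance.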
